A study of Triticum aestivum with 36 samples.

How the data were processed

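RNA of flag leaves was measured on the Affymetrix wheat array, 36 arrays in all. Per the labels, 2 F6 recombinant inbred lines, 1 with Yr39 and 1 with the alternative allele yr39, were inoculated with race PST-78 or mock-inoculated and harvested 12, 24 and 48 h later, with 3 biological replicates. Plants grew at 10 to 25 °C with 16 h light and 8 h dark, with 8 pots of 3 seedlings per line and replication and 2 pots per harvest, and flag leaves were used at about day 35 (Feekes 9). The titles, source names and genotype fields give the line and were used. The description field gives the yr39 line for all arrays titled yr39 and also for 12 of the 18 titled Yr39. The probe set Ta.27757.1.S1_at was between 51846 and 81297 on those 12, between 44057 and 76171 on the other 6, and between 4.81 and 136.5 on the 18 titled yr39, so the 12 were grouped as titled. That probe set was picked as the one most above yr39 in the mock arrays titled Yr39. Of the 12 arrays 9 are inoculated and did not enter that difference. Which of the lines carries the resistance rests on the titles. RNA was extracted with Trizol and labelled with biotin. The values are the intensity signals the authors deposited, which the submitters' processing notes credit to MAS5, with a version not given in the sources used here. The deposited intensity values are on a linear scale, and the 2% trimmed mean of each array was 500.3. All sample columns were used, and no array column was identical to another.

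Groups were read from the sample titles, which give line, treatment, time and replicate number. The growth notes say that each of the 3 biological replications planted both lines, but the labels do not state outright that the replicate number is the planting. Arrays with the same number were therefore treated as pairs only for counting directions and in an alternative with replicate number as a block. After group means were removed, arrays of the same number correlated with a mean r of 0.097 (between −0.158 and 0.311) and arrays of other numbers with −0.048. The block counts and these correlations were first seen together.

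Of 61290 probe sets 111 controls with AFFX names were left out. Signals were transformed as log2(signal + 16), and the 44403 of 61179 probe sets at or above their array's median on at least 3 arrays were tested. A linear model with 12 group means (24 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. Contrasts were inoculated against mock in each line at each time and over the 3 times, the difference of these between the lines, the change of the response with time in each line (an F test), the lines in mock leaves, and the steps from 12 to 24 h and from 24 to 48 h in mock leaves. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe set with an adjusted p under 0.05 is said to be called. SE is the moderated standard error of a log2 change. A log2 change against a group near background depends on the pseudocount.

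Gene symbols came from the platform annotation, which paired 1273 probe sets with 1 symbol each and none with several, while 59906 were not listed and are given by probe set name. They stand for 771 genes, of which 682 were measured, and 1272 of the 1273 were matched to the reference gene table by gene identifier. Only 102 genes, 84 of them tested, have a name beyond a LOC number, and no function was assigned to the others. Wheat has related gene copies, and probe sets ending in _s_at or _x_at can detect more than 1 of them. A gene with several probe sets is given by the brightest over the 36 arrays. Another probe set of the histone gene H2A-3 (LOC732713) was called in the opposite direction from 24 to 48 h. Named in the text are up to 10 genes per direction in contrasts averaged over several groups and up to 5 in single-time contrasts, by size of change among called genes, and up to 2 probe sets without a symbol per direction. That the mock time steps count as averaged contrasts was settled after their values were seen, and other probe sets are marked as chosen after their values were seen.

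Of 23 gene lists fixed before the data were examined, 5 had a measured gene and 0 had the 5 genes needed for a test as a group. Groups by gene symbol were formed after the names and before any values were seen: photosynthesis, core histones, tubulins, grain storage, defence and redox, translation, serpins and enzyme inhibitors, LEA, fructan, gibberellin 20-oxidases and raftins. Groups with at least 5 measured genes were tested among the 682 genes with camera in limma, at a preset correlation of 0.01 and adjusted over the groups of a contrast.

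The settings varied were pseudocounts of 1 and 64, quantile normalization, no filter, a filter on the mean signal (30590 probe sets), no trend, replicate number as a block, only the arrays compared, and each array left out. After the data were seen, contrasts of inoculated against mock at 48 hpi over both lines and over all times, of the lines in inoculated leaves and of the time steps in inoculated leaves were added, and an alternative without arrays numbered 1. Planted changes were tested on simulated data, 200 per run in 3 runs, with the measured mean and spread of each probe set and independent noise. For lines in mock leaves 37.3% of 2-fold and 86.7% of 4-fold changes were recovered, with 7.3 false calls per run. From 24 to 48 h in mock leaves it was 26.7% and 71.3%, with 3.7 false calls, and in the Yr39 line at 48 hpi there were 4.3 among 65.7 calls per run. Camera called 3.0% of 200 random groups of 7 genes at unadjusted p under 0.05, and all groups moved by 1 log2 unit. The simulated genes were not correlated and the simulated arrays had no replicate effect, so these rates may not hold for the measured data. The measured photosynthesis genes had an estimated correlation of 0.766.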

Results

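Flag leaves of 2 wheat lines were profiled after inoculation with the stripe rust fungus, race PST-78, or after mock inoculation. Both were F6 recombinant inbred lines from Alpowa, 1 carrying the resistance gene Yr39 and the other the alternative allele yr39. Leaves were taken 12, 24 and 48 h after inoculation (hpi), with 3 biological replicates in each of the 12 groups and 36 arrays in all. Of 61179 wheat probe sets 44403 were tested, and 682 genes with a symbol were measured by 1061 of them. The median signal of an array was 88.4 ± 12.4 (SD, n = 36), between 67.6 and 118.7, and arrays of the same group correlated with r between 0.872 and 0.946. Time separated the arrays most. The first principal component held 29.0% of the variance, with scores of 123.44 ± 24.19 at 48 hpi, −42.42 ± 15.52 at 12 hpi and −81.02 ± 22.71 at 24 hpi (SD, n = 12). The second component held 7.86%, with a mean score of 52.47 for arrays numbered replicate 1 and of −27.41 and −25.06 for replicates 2 and 3. The mean log2 signal of the hybridization controls was 11.74, 11.72 and 12.07 at 12, 24 and 48 hpi, and 12.21, 11.66 and 11.65 for replicates 1, 2 and 3. The log2 ratio of 3′ to 5′ signal was −1.27, −1.37 and −1.50 for ubiquitin and −1.53, −2.30 and −1.17 for GAPDH at the 3 times, with single arrays between −4.71 and 1.29 for GAPDH.

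**Figure D1:**
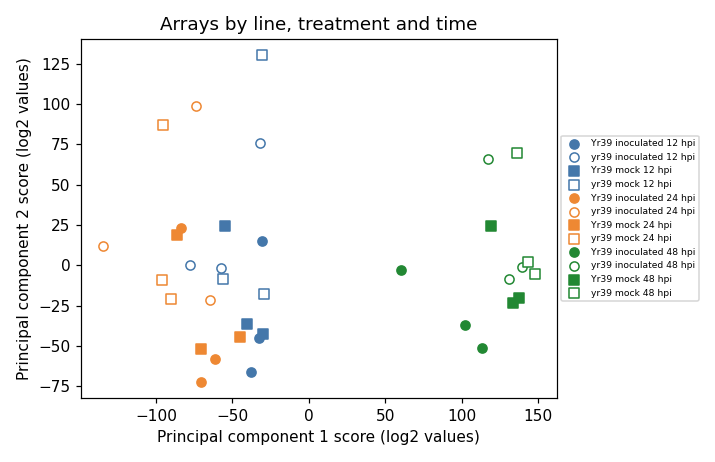
Scores of the 36 arrays on the first and second principal components, from log2(signal + 16) of the tested probe sets. Colour gives the time (blue 12, orange 24, green 48 hpi), circles are inoculated and squares mock, filled symbols are the Yr39 line and open symbols the yr39 line.

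Inoculated and mock leaves of the resistant line were compared at each time to find transcripts that responded to the fungus. Here and below a rise or fall with inoculation means a higher or lower signal than in mock leaves of the same time. At 48 hpi LOC542838 had a signal of 20677 ± 4628 in inoculated and 8528 ± 698 in mock Yr39 leaves (SD, n = 3), higher by 1.26 log2 units (SE 0.202, adjusted p = 0.0103). On single arrays at 24 hpi it was 26792 to 34990 in inoculated and 26364 to 34535 in mock Yr39 leaves, so by 48 hpi it had fallen less in inoculated leaves. Ta.22669.1.A1_at rose by 3.30 (SE 0.593, adjusted p = 0.0330), from 135 ± 179 to 1055 ± 678. Ta.9415.2.A1_a_at rose by 2.59 (SE 0.390, adjusted p = 0.00856), from 12.4 ± 5.2 to 173 ± 112. The last of these was present at 1345 to 1623 in every group of the yr39 line. Chosen after their values were seen, Ta.11660.1.S1_at rose by 1.46 (adjusted p = 0.0330), Ta.21297.1.S1_at by 2.30 (adjusted p = 0.0103) and Ta.5125.3.S1_at by 2.39 (adjusted p = 0.0168). Each of the 6 was higher in 3 of 3 replicates, and these 6 were all that limma called, with 0 lower and 2694 at unadjusted p under 0.05 where 2220 were expected by chance. The same 2220 are expected in every contrast. All other planned contrasts of inoculation, the interactions included, had fewer, down to 980. The excess of 2694 is therefore not by itself evidence of a response. In the yr39 line LOC542838 differed by 0.51 (SE 0.202, adjusted p = 1.0), with a signal of 9852 in inoculated and 6857 in mock leaves. The interaction of line and inoculation was 0.75 for LOC542838 (SE 0.286, adjusted p = 1.0) and 2.74 for Ta.9415.2.A1_a_at (SE 0.551, adjusted p = 0.501), and 1.0 was the adjusted p for each of the other 4.

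The call of LOC542838 at 48 hpi was lost when inoculated replicate 1, inoculated replicate 2, mock replicate 2 or mock replicate 3 of the Yr39 line was left out (adjusted p between 0.0924 and 0.226). Without any of the same 4 arrays Ta.22669.1.A1_at (0.138 to 0.541), Ta.21297.1.S1_at (0.0991 to 0.154) and Ta.5125.3.S1_at (0.117 to 0.354) were not called. Ta.9415.2.A1_a_at was lost without inoculated replicate 1 or mock replicate 3 (0.0924 to 0.154), and Ta.11660.1.S1_at without inoculated replicate 1 or 2 or mock replicate 3 (0.120 to 0.598). The number of calls was 0, 1 and 16 without inoculated replicates 1, 2 and 3, and 57, 2 and 0 without mock replicates 1, 2 and 3. LOC542838 was not called after quantile normalization (log2 1.27, adjusted p = 0.104) or from the arrays of its own groups alone (adjusted p = 0.0946). From those arrays alone Ta.22669.1.A1_at (0.305), Ta.9415.2.A1_a_at (0.216), Ta.11660.1.S1_at (0.346) and Ta.5125.3.S1_at (0.324) were lost too, and Ta.21297.1.S1_at was the only 1 of the 6 still called. With log2(signal + 64) Ta.22669.1.A1_at (0.0537), Ta.11660.1.S1_at (0.0537) and Ta.5125.3.S1_at (0.167) were lost, and without the intensity trend Ta.22669.1.A1_at (0.0876) and Ta.11660.1.S1_at (0.0674). With replicate number as a block 23 probe sets were called. In a planted test of this comparison limma recovered 10.3% of 2-fold and 51.0% of 4-fold changes, 81.5% of the 4-fold changes among brighter and 16.6% among dimmer probe sets. A run of that test called 65.7 probe sets and the measured comparison 6. The adjustment is stricter where fewer are called, so recovery may be lower in the measured data.

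None of 7 photosynthesis genes was called between inoculated and mock Yr39 leaves at 48 hpi by limma, which had 2694 probe sets at unadjusted p under 0.05. PsbP and PsbO of the oxygen-evolving complex, PRK and FBP of the Calvin cycle, petC, Trx-M and rbcL differed by −0.41 to −0.24 with a median of −0.30. As a group their adjusted p was 0.0297 in camera, but 0.445 with an estimated correlation and 0.672 after quantile normalization, so a shift of the group is not shown, and in the yr39 line the camera adjusted p was 0.791. The interaction at 48 hpi gave 0.192.

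PR5, a thaumatin-like pathogenesis-related gene (LOC543292), had a signal of 11696 ± 4951 in inoculated and 2583 ± 1872 in mock Yr39 leaves at 48 hpi and was not called (log2 2.33, SE 1.21, adjusted p = 0.859). At 12 and 24 hpi limma called 0 probe sets in the Yr39 line, with 1013 and 1172 at unadjusted p under 0.05, below the 2220 expected by chance. Averaged over the 3 times it called 0, with 1641 at unadjusted p under 0.05 and a smallest adjusted p of 0.814. TaAffx.32249.1.S1_at, called in the yr39 line, was higher in 8 of 9 inoculated Yr39 leaves (log2 1.77, adjusted p = 0.814). The test for a response of the Yr39 line that changed with time called 0, with 1414 at unadjusted p under 0.05, and 1 with replicate number as a block.

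In the yr39 line the same comparison at 48 hpi called Ta.23271.1.S1_s_at alone. Its signal was 2040.0 ± 600.5 in inoculated and 331 ± 141 in mock leaves (SD, n = 3), and it rose by 2.60 (SE 0.359, adjusted p = 0.00169, 3 of 3 replicates). In mock yr39 leaves at 24 hpi the signal of Ta.23271.1.S1_s_at was 23660.0 ± 1175. In Yr39 leaves at 48 hpi it was 21486 ± 5533 inoculated and 7716 ± 2907 mock (log2 1.503, SE 0.359, adjusted p = 0.171), and the interaction was −1.10 (SE 0.508, adjusted p = 1.0). At unadjusted p under 0.05 there were 1759 probe sets at 48 hpi. The call held without any single array, while the number called was 7 without inoculated replicate 1 and 2 without inoculated replicate 2, inoculated replicate 3 or mock replicate 1. From the arrays of its own groups alone Ta.23271.1.S1_s_at was not called (adjusted p = 0.195). It was also the only probe set whose inoculation response changed with time in the yr39 line (adjusted p = 0.0488), and this was lost without any one of 13 of the 18 arrays, adjusted p between 0.0604 and 0.504. This limma test over time had 1317 at unadjusted p under 0.05.

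**Figure D2:**
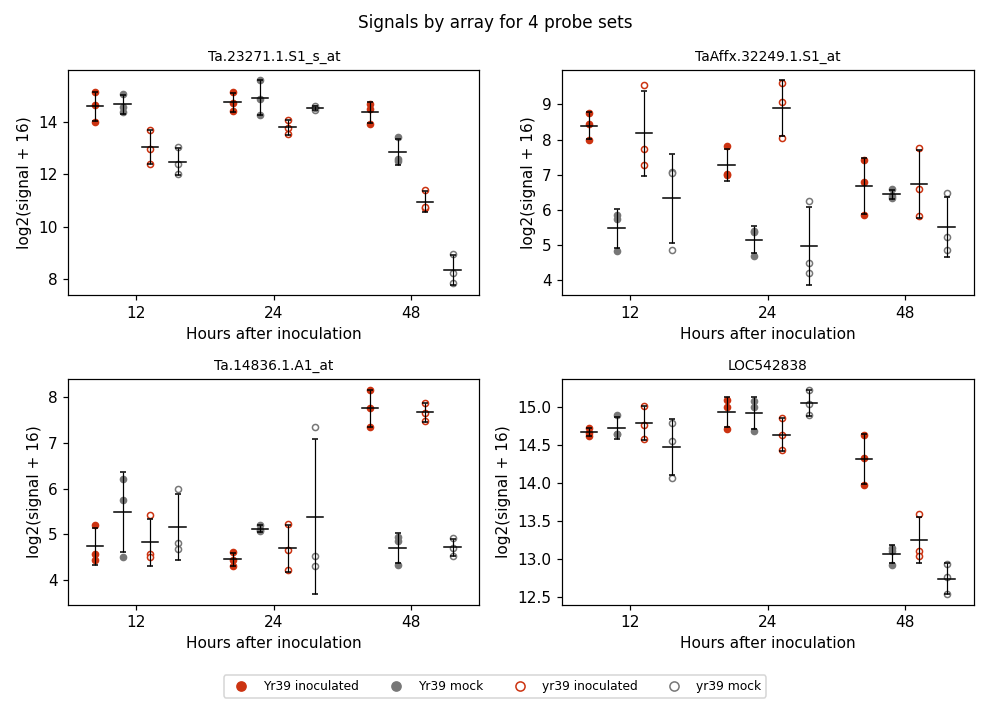
Log2(signal + 16) of Ta.23271.1.S1_s_at, TaAffx.32249.1.S1_at, Ta.14836.1.A1_at and LOC542838 against hours after inoculation. Points are arrays, bars are group means and error bars SD (n = 3). Red is inoculated and grey mock, filled symbols are the Yr39 line and open symbols the yr39 line.

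At 24 hpi TaAffx.32249.1.S1_at was the only call in the yr39 line, with a signal of 511 ± 259 in inoculated and 22.9 ± 32.4 in mock leaves (log2 3.93, SE 0.647, adjusted p = 0.0438, 3 of 3 replicates). The Yr39 line had 145 and 20.3 (log2 2.13, SE 0.647, adjusted p = 1.0), and the interaction was −1.81 (SE 0.916, adjusted p = 1.0). Averaged over the 3 times TaAffx.32249.1.S1_at was again the only call in the yr39 line, with a rise of 2.33 (SE 0.374, adjusted p = 0.0274), higher in 9 of 9 replicates, and an interaction of −0.56 (SE 0.529, adjusted p = 1.0). At unadjusted p under 0.05 limma had 1293 probe sets at 24 hpi and 1949 over the 3 times. At 12 hpi it called 0 in this line, with 1804 at unadjusted p under 0.05, and 1 without mock replicate 1.

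At 24 hpi the call of TaAffx.32249.1.S1_at was lost without inoculated replicate 1 or 2 or mock replicate 2 or 3 of the yr39 line (adjusted p between 0.106 and 0.405). The number of calls was 0 without inoculated replicate 1 or mock replicate 2 or 3, 3 without inoculated replicate 2, and 2 without mock replicate 1. The call over the 3 times was lost without any one of 10 of the 18 arrays, adjusted p between 0.0551 and 0.145. With log2(signal + 1) the adjusted p of TaAffx.32249.1.S1_at was 0.0688 at 24 hpi and 0.0750 over the 3 times. From the arrays of the groups compared alone it was 0.9999 and 0.724.

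A difference between the lines in their response was tested directly as the interaction of line and inoculation. The response of Ta.9415.2.A1_a_at at 48 hpi differed between the lines by 2.74 and that of LOC542838 by 0.75, and neither they nor Ta.23271.1.S1_s_at or TaAffx.32249.1.S1_at were called. With limma 0 probe sets were called at 12, 24 and 48 hpi, with 1107, 980.0 and 1457 at unadjusted p under 0.05 and smallest adjusted p of 0.706, 1.0 and 0.501. Each of these counts was below the 2220 expected by chance. Without mock replicate 2 of the yr39 line 1 was called at 24 hpi, and with log2(signal + 1) 2 were called at 48 hpi. The interaction averaged over the 3 times called 0, with 1216 at unadjusted p under 0.05. The planted test of this average recovered 17.0% of 2-fold and 53.3% of 4-fold changes, with 73.3 calls per run, so recovery may be lower in the measured data. Across probe sets the inoculation changes of the 2 lines correlated with r = 0.043, 0.073 and 0.137 at 12, 24 and 48 hpi, and with r = 0.163, 0.215 and 0.377 among the 22202 brighter ones.

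The lines themselves differed without the fungus. Over mock leaves of all 3 times the gibberellin 20-oxidase gene GA20ox1D (LOC543325), which acts in gibberellin synthesis, was higher in Yr39 than in yr39 leaves (294 ± 112 and 159 ± 177, SD, n = 9; log2 1.57, SE 0.341, adjusted p = 0.00627, 8 of 9 pairs). GA20ox1A (LOC543327) was higher by 1.30 (adjusted p = 0.0437, 8 of 9 pairs), and GA20ox1B (LOC543326) had 1.16 and was not called (adjusted p = 0.211). With log2(signal + 1) and log2(signal + 64) the difference was 1.95 and 1.05 for GA20ox1D and 1.77 and 0.83 for GA20ox1A. LOC780647 had the smallest p among listed genes (1807 ± 174 and 817 ± 143, log2 1.15, SE 0.117, adjusted p = 1.95e-08, 9 of 9 pairs). Also higher in the Yr39 line were LOC543152 (1.498, adjusted p = 0.0234), LOC780599 (1.37, 0.00145), LOC543018 (1.06, 0.00308), LOC606363 (0.87, 0.00892), LOC100125710 (0.68, 0.0295), LOC100049037 (0.57, 0.0387) and LOC543362 (0.43, 0.0481), each in 8 or 9 of 9 pairs. Lower in the Yr39 line were LOC542853 (9996 ± 17609 and 24407 ± 14481, log2 −2.77, SE 0.319, adjusted p = 2.50e-07, 8 of 9 pairs), LOC542898 (−1.95, 4.49e-05), LOC543399 (−1.75, 2.98e-06) and LOC542814 (−0.76, 0.00149), the last 3 in 9 of 9.

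Some probe sets without a listed gene were near background in 1 line. Ta.27757.1.S1_at (log2 9.95, adjusted p = 8.42e-23) and Ta.23366.2.S1_at (8.15) had signals of 56.4 and 19.3 in the yr39 line against 58375 and 11428. Ta.23165.2.S1_x_at (−7.93) and Ta.30807.3.S1_at (−7.74) had 20.8 and 54.0 in the Yr39 line against 14236 and 13846, all 4 in 9 of 9 pairs. The size of these 4 differences depends on the pseudocount, and with log2(signal + 64) it was 9.003, 6.83, −6.68 and −6.74. In all limma called 796 probe sets, 467 higher and 329 lower in the Yr39 line, 551 of them by more than 2-fold, and 4471 at unadjusted p under 0.05. Among the 682 listed genes 12 were higher and 4 lower.

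GA20ox1D kept its call without any single array, as did LOC780599, LOC780647, LOC542853, LOC542898, LOC543399 and LOC542814. GA20ox1A lost its call without any one of 14 of the 18 arrays, adjusted p between 0.0553 and 0.138, and its adjusted p was 0.0597 with log2(signal + 1), 0.0644 without the signal filter and 0.0526 from mock arrays alone. LOC543152 lost its call without any one of 7 of the 18 arrays (0.0527 to 0.0732) and LOC543362 without any one of 17 (0.0517 to 0.159). LOC100125710 lost it without any one of 9 (0.0504 to 0.0875) and LOC100049037 without any one of 12 (0.0502 to 0.123). Without all arrays numbered 1 the difference of LOC543152 was 0.87 (adjusted p = 0.338), of LOC100125710 0.46 (0.219), of LOC100049037 0.44 (0.253), of LOC543362 0.42 (0.201) and of GA20ox1A 1.52 (0.0727), and none of these was called. Without the intensity trend LOC100125710 (0.0634), LOC100049037 (0.0729) and LOC543362 (0.0673) lost their calls, and from mock arrays alone LOC100049037 (0.0625) and LOC543362 (0.133). LOC543362 was also not called after quantile normalization (adjusted p = 0.0645).

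**Figure D3:**
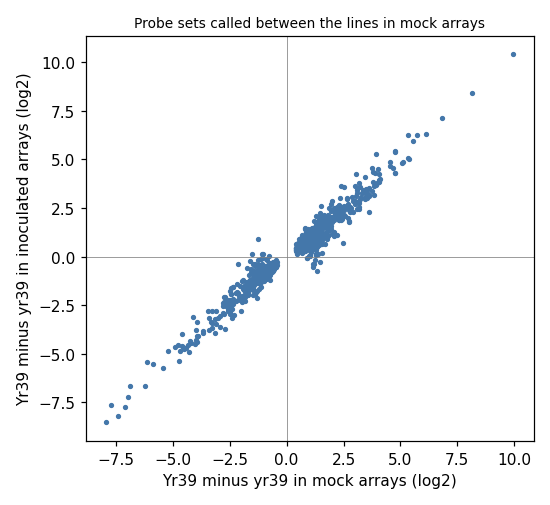
Yr39 minus yr39 difference (log2) in mock and in inoculated leaves for the 796 probe sets called in mock leaves. Each point is a probe set and each axis is a mean over the 3 times.

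Mock leaves were followed from 12 to 24 h to describe change without the fungus. PEAMT1 (LOC543067), a phosphoethanolamine methyltransferase of phosphocholine synthesis, fell from 1767 ± 690 to 723 ± 375 (SD, n = 6; log2 −1.40, SE 0.334, adjusted p = 0.0144, 6 of 6 pairs). Prx1 (LOC606328) fell from 8497 to 3994 (−1.29, SE 0.320, adjusted p = 0.0186) and LOC542862 from 1337 to 428 (−1.60, SE 0.315, adjusted p = 0.00313). LOC606369 rose from 5060 to 12454 (1.42, SE 0.343, adjusted p = 0.0153). Other genes that rose were LOC543237 (2.01, adjusted p = 0.0420), LOC543100 (1.38, 0.00659), LOC780574 (1.32, 0.00364), LOC778392 (1.08, 0.0345), LOC780670 (1.02, 0.0410), LOC778397 (0.56), LOC543170 (0.54), LOC100037597 (0.52) and LOC542911 (0.40). Other genes that fell were LOC542782 (−1.37, 0.0121), LOC543004 (−1.29, 0.0468), LOC100037541 (−1.29, 0.0177), LOC778385 (−1.10, 0.0121), LOC100037649 (−1.06, 0.00491), LOC543355 (−1.02, 0.00766) and LOC543186 (−1.004, 0.00188), in 6 of 6 pairs each, as were the genes that rose except LOC780670 (5 of 6). The largest changes without a listed gene were Ta.28289.1.S1_a_at (3.92), Ta.1575.1.S1_at (3.83), Ta.17978.1.S1_at (−4.25) and Ta.9590.1.S1_at (−4.11). In all limma called 1450 probe sets, 452 higher and 998 lower at 24 h, 733 of them by more than 2-fold, and 6333 at unadjusted p under 0.05.

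Of 7 photosynthesis genes 2 were called from 12 to 24 h in mock leaves. FBP (fructose-1,6-bisphosphatase) fell by 0.65 (adjusted p = 0.0161) and PsbO by 0.70 (adjusted p = 0.0261), while PRK (LOC543283; −0.75, 0.0532), PsbP (LOC543290; −0.65, 0.0906) and Trx-M (−0.51, 0.0555) were not called and petC (−0.12) and rbcL (0.05) changed little. As a group the adjusted p was 0.000568 in camera, 0.521 with an estimated correlation and 0.0531 with all probe sets of the genes. FBP lost its call without mock 12 h replicate 1 or mock 24 h replicate 2 of the yr39 line or mock 24 h replicate 2 of the Yr39 line (adjusted p between 0.05002 and 0.0577). PsbO lost it without any one of 5 of the 12 arrays (0.0684 to 0.0864), namely the same 3 and Yr39 mock 12 h replicates 1 and 3. The GAPDH ratio of 3′ to 5′ signal was −1.53 at 12 hpi and −2.30 at 24 hpi.

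PEAMT1 lost its 24 h call without yr39 mock 24 h replicate 2 or Yr39 mock 24 h replicate 1 (adjusted p between 0.0515 and 0.0715). Prx1 lost it without yr39 mock 24 h replicate 2, Yr39 mock 12 h replicate 3 or Yr39 mock 24 h replicate 3 (0.0602 to 0.0803), LOC606369 without yr39 mock 12 h replicate 3 (0.0566) and LOC778385 without yr39 mock 24 h replicate 2 (0.0592). LOC543237 and LOC780670 lost their calls without any one of 10 of the 12 arrays, LOC543004 without any one of 9, LOC778392, LOC778397 and LOC100037597 without any one of 8 and Ta.17978.1.S1_at without any one of 7. LOC100037541 and LOC543170 lost theirs without Yr39 mock 12 h replicate 1, Yr39 mock 24 h replicate 2 or 3 or yr39 mock 12 h replicate 1. LOC100037541 (0.0514 to 0.0684) also lost it without yr39 mock 24 h replicate 3, and LOC543170 (0.0525 to 0.0842) without yr39 mock 24 h replicate 2. LOC542911 lost it without yr39 mock 12 h replicate 1, yr39 mock 24 h replicate 1 or 2, Yr39 mock 12 h replicate 3 or Yr39 mock 24 h replicate 2 (0.0525 to 0.0799). Without Yr39 mock 12 h replicate 3, Yr39 mock 24 h replicate 2 or yr39 mock 24 h replicate 2 the number of calls was 901, 905 and 845, and from the arrays of the 2 times alone it was 689. PEAMT1 (adjusted p = 0.0786), Prx1 (0.149) and FBP (0.0747) were among the genes not called from those arrays alone.

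From 24 to 48 h mock leaves changed most of all. PEAMT1 turned and rose from 723 ± 375 to 19230.2 ± 2191 (SD, n = 6), 4.77 log2 units above the median probe set (SE 0.334, adjusted p = 4.82e-13). LOC606310 rose from 26.7 ± 17.6 to 4113 ± 1543 (6.47, SE 0.426, adjusted p = 1.42e-13) and LOC100037609 from 4881 to 59684 (3.48, SE 0.198, adjusted p = 5.19e-15). LOC606391 fell from 12927 ± 7628 to 91.0 ± 53.2 (−6.99, SE 0.399, adjusted p = 1.65e-14). LOC606312 (5.26), LOC543256 (4.58), LOC542846 (4.37), LOC543421 (4.34), LOC543368 (3.58), LOC542859 (3.36) and LOC543127 (3.29) also rose. LOC543383 (−5.71), LOC778415 (−5.26), LOC606308 (−5.26), LOC542781 (−4.98), LOC543201 (−4.72), LOC100037518 (−4.71), LOC543287 (−4.11), LOC606369 (−4.06) and LOC543197 (−3.84) fell. All of these were seen in 6 of 6 pairs and kept their calls without any single array. Of probe sets without a listed gene Ta.18654.1.S1_at (7.58) and Ta.3249.3.A1_at (6.41) rose and Ta.22766.1.S1_at (−8.45) and Ta.8571.1.S1_x_at (−7.42) fell most. In all limma called 15456 probe sets, 8434 higher and 7022 lower at 48 h, 10199 of them by more than 2-fold, and 18726 at unadjusted p under 0.05. The median change over all tested probe sets was 0.13, and changes from 24 to 48 h are given relative to it in this paragraph and for the gene groups that follow. The p-values and SE belong to the changes before this reduction. After quantile normalization the median change was 0.02, with 15162 called.

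From 24 to 48 h 6 of 7 photosynthesis genes rose in mock leaves. PsbP (1.36, adjusted p = 8.75e-07), PRK (1.31, 2.93e-06), PsbO (1.17, 7.00e-07), Trx-M (1.16, 2.66e-08) and FBP (1.07, 2.64e-07) rose in 6 of 6 pairs. The Rieske protein gene petC rose by 0.57 before the median was taken off (adjusted p = 0.0153) and by 0.44 after, but changed by −0.08 after quantile normalization, and its call was lost without Yr39 mock 24 h replicate 2 (adjusted p = 0.0551). Quantile normalization thus moved petC by more than the median did, so taking off the median need not correct the other sizes in full. The Rubisco gene rbcL had 0.21 and was not called (adjusted p = 0.178). As a group the camera adjusted p was 0.00268, 0.336 with an estimated correlation, 0.0951 after quantile normalization and 0.0681 with all probe sets of the genes. GA20ox1B (1.72, adjusted p = 0.00371), GA20ox1A (1.54, 0.00214) and GA20ox1D (1.52, 0.00200) all rose, GA20ox1B (LOC543326) and GA20ox1A in 5 of 6 pairs, and without all arrays numbered 1 the adjusted p of GA20ox1B was 0.0601. The hybridization controls were brighter at 48 than at 24 hpi (12.07 and 11.72), and the ratio of 3′ to 5′ signal was −1.50 and −1.37 for ubiquitin and −1.17 and −2.30 for GAPDH.

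**Figure D4:**
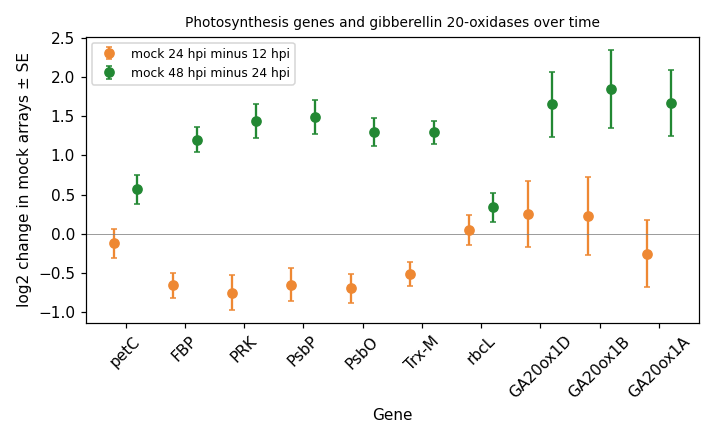
Change in mock leaves (log2 ± SE, n = 6 arrays per time) of 7 photosynthesis genes and 3 gibberellin 20-oxidase genes, orange for 24 minus 12 h and green for 48 minus 24 h. The changes are not reduced by the median change. The change of petC from 24 to 48 h was −0.08 after quantile normalization.

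Among other named groups from 24 to 48 h the tubulins tubb2 (−2.30, adjusted p = 2.98e-06), tubb3 (−2.24, 1.25e-08) and TUBA (−1.27, 1.64e-07) fell and Tubb5 rose (0.78, 0.00509). The histones H2B-8 (3.25, 4.82e-11) and H2B-6 (1.03, 0.000958) rose, 2 of 5 measured. In both groups the camera adjusted p was 0.238, and 0.336 with an estimated correlation. With all probe sets of the genes, at the preset correlation, it was 0.00885 for the histones and 0.492 for the tubulins. Prx1 (2.27, 3.08e-07) and the catalase CAT1 (1.12, 4.02e-05) rose. Glc1 fell (−2.33, 2.83e-09), and so did the lignin-pathway gene COMT1 (−0.96, 0.0495), whose call was lost without any one of 8 of the 12 arrays, adjusted p between 0.0694 and 0.173. The camera adjusted p of the 8 defence and redox genes was 0.992. RPL9 (1.68, 2.70e-07) rose and the initiation factors eIF4B (−1.30, 2.09e-07) and eIF4E (−0.69, 0.000134) fell. TCTP (LOC542949) rose by 0.33 before the median was taken off (SE 0.118, adjusted p = 0.0266) and was 0.21 above the median, a difference that was not tested, but changed by −0.26 after quantile normalization, and its call was lost without mock 24 h replicate 2 or mock 48 h replicate 1 of the Yr39 line or mock 24 h replicate 3 or mock 48 h replicate 1 of the yr39 line (0.0599 to 0.0799). The camera adjusted p of the 8 translation genes was 0.776. The xylanase inhibitor XIP-I fell (−3.14, 1.40e-12) and the anther gene raftin1b rose (1.25, 0.00764). With limma 0 of 6 grain storage genes were called, and the camera adjusted p of that group was 0.992. The hybridization controls had a mean log2 signal of 12.07 at 48 hpi against 11.72 at 24 hpi, and the GAPDH ratio of 3′ to 5′ signal was −1.17 against −2.30.

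Of the gene lists fixed in advance, 5 had a single measured gene each, and their changes are given without taking off a median. PR5, for pathogenesis-related genes, ranged from −1.73 to 2.33 over the comparisons, with a smallest adjusted p of 0.143 from 24 to 48 h in mock leaves. There it was 0.0489 from the arrays of the 2 times alone, 0.0428 without Yr39 mock 24 h replicate 3 and 0.00926 without all arrays numbered 1. The peroxidase gene PER1 ranged from −0.83 to 0.71 (smallest adjusted p 0.259), GSTZ1 for glutathione transferases from −0.14 to 0.33 (0.306), Serpin-Z2A for protease inhibitors from −1.42 to 0.38 (0.543) and the LEA gene LOC543476 from −1.25 to 1.01 (0.836). Adjusted over these 5 genes alone, the smallest limma value of Serpin-Z2A over the comparisons was 0.0476, which need not be from the comparison that gave 0.543. None of the 5 was called in any of the 15 planned comparisons when adjusted over all tested probe sets.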

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

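The test of whether the inoculation response changed with time was planned, while leaving out all arrays numbered 1 and counting other splits were chosen only after the result was seen. Ta.23271.1.S1_s_at in the yr39 line stood out because its response differed between the times (limma F test, adjusted p = 0.0488). Inoculated leaves were lower than mock leaves at 24 hpi (14282 and 23660.0) and higher at 48 hpi (2040.0 and 331). The adjusted p was 0.0924 with log2(signal + 64), 0.0508 without a filter, 0.152 without the intensity trend and 0.351 without all arrays numbered 1, and it passed 0.05 without any one of 13 of the 18 arrays (0.0604 to 0.504). Other splits of these arrays called as many probe sets often (see the counts below), so the difference between times stays uncertain. Single arrays were examined by leaving each out in turn, and no test for an outlying array within a group of 3 was run.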

How the results depend on the processing

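The alternative without arrays numbered 1 and the contrasts over both lines or in inoculated leaves alone were chosen only after the results were seen. The response of the Yr39 line at 48 hpi moved from 6 calls to 23 with replicate number as a block, 20 from only the arrays compared (1 of the 6 among them) and 55 without arrays numbered 1. In the yr39 line 1 was called at 12 hpi without arrays numbered 1. At 24 hpi the 1 call became 0 with log2(signal + 1), without a filter, without the trend, from only the arrays compared and without arrays numbered 1. At 48 hpi the 1 call became 3 with log2(signal + 1), 2 with log2(signal + 64), 2 without a filter, 0 from only the arrays compared and 5 without arrays numbered 1. Over the 3 times the 1 call became 2 after quantile normalization or with log2(signal + 64), and 0 with log2(signal + 1), from only the arrays compared and without arrays numbered 1. The interaction at 48 hpi had 2 calls with log2(signal + 1). The change of the response with time had 1 call in the Yr39 line with the block and 3 without arrays numbered 1, and 0 in the yr39 line with log2(signal + 64), without a filter, with the mean filter, without the trend, from only the arrays compared and without arrays numbered 1. From 12 to 24 h in mock leaves 689 were called from only the arrays compared.

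With each array left out in turn the Yr39 line had 0 to 0 calls at 12 and at 24 hpi and 0 to 57 at 48 hpi, and the yr39 line 0 to 1, 0 to 3 and 1 to 7. The interactions had 0 to 0, 0 to 1 and 0 to 0, and 0 to 0 over the times. Over the times the Yr39 line had 0 to 0 and the yr39 line 0 to 1, and the change with time 0 to 3 and 0 to 2. The lines in mock leaves had 646 to 888 calls, and the mock time steps 845 to 1386 and 14215 to 14990. The contrasts added later had 8 to 89 at 48 hpi over both lines, 1 to 4 over lines and times, 776 to 1186 for the lines in inoculated leaves, and 904 to 1649 and 12039 to 13240 for the inoculated time steps. Without arrays numbered 1, 16 were called over lines and times.

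Of 153 values of single genes or probe sets, 86 kept their side of the threshold and direction in all settings, and the block changed none. Calls were lost for 44 from only the arrays compared, 39 without the trend, 25 without arrays numbered 1, 21 without a filter, 9 with each other pseudocount, 2 with the mean filter and, in the same direction, 5 after quantile normalization, where petC was lost too. From 24 to 48 h in mock leaves (changes without the median taken off) the direction turned after quantile normalization for TCTP (LOC542949; −0.257) and petC (−0.083), and for GSTZ1 (LOC543412; −0.001) without arrays numbered 1. The LEA gene LOC543476 turned to −0.112, −0.080 and −0.079 without yr39 mock 48 h replicate 3, Yr39 mock 24 h replicate 1 and Yr39 mock 48 h replicate 3, and was highest, at 0.532, without Yr39 mock 48 h replicate 1. The grain storage group turned with all probe sets (camera adjusted p = 0.920). Uncalled genes of the fixed lists, and photosynthesis genes in uncalled contrasts, also changed direction in some settings. Lists with too few genes could not be tested as groups. The cause was not tested for any of these changes.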

Other observations

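All contrasts over both lines or in inoculated leaves, all counts of other splits, and the tests of the patterns below were chosen after the results were seen, except those of hybridization brightness, of RNA integrity by the ubiquitin ratio and of scaling for the Yr39 line at 48 hpi.

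Averaged over both lines at 48 hpi, inoculation raised Ta.14836.1.A1_at from 10.3 ± 4.2 to 198 ± 44.7 (SD, n = 6; log2 3.01, SE 0.406, adjusted p = 0.000528, 6 of 6 pairs). LOC542838 rose from 7692 to 15265 (0.88, SE 0.143, adjusted p = 0.00690), and Ta.23271.1.S1_s_at (2.05, adjusted p = 0.000179), Ta.21297.1.S1_at (1.78, 0.00154) and Ta.22669.1.A1_at (2.55, 0.00717) rose too. Ta.11160.1.S1_s_at fell from 168 to 23.4 (−2.13, SE 0.336, adjusted p = 0.00526). These 6 kept their calls without any single array and changed in 6 of 6 pairs, but Ta.22669.1.A1_at was not called from only the arrays compared (adjusted p = 0.0757). From 24 to 48 h in mock leaves LOC542838 (−2.09, median not taken off), Ta.23271.1.S1_s_at (−4.11), Ta.21297.1.S1_at (−5.16) and Ta.22669.1.A1_at (−5.45) fell and Ta.11160.1.S1_s_at rose (2.52). Ta.14836.1.A1_at was not called there (−0.55). For those called over time, a smaller change with time in inoculated leaves cannot be told apart from induction or repression. A dimmer probe set of LOC778392, chosen after its values were seen, rose by 1.13 (adjusted p = 0.0322), while the brightest of this gene was not called. The dimmer probe set lost its call without any one of 8 of the 12 arrays (0.0522 to 0.153). Ta.23324.1.S1_at (2.66, 0.0462) and TaAffx.59330.1.S1_at (−1.85, 0.0414) lost theirs without any one of 10. In all limma called 26 probe sets, 24 higher and 2 lower, 80 with replicate number as a block, and 2968 at unadjusted p under 0.05. Without the intensity trend 9 were called, with 17 of the 26 lost, the dimmer probe set of LOC778392 (adjusted p = 0.0967) and Ta.23324.1.S1_at (0.116) among them. It was 40 after quantile normalization, 46 with log2(signal + 1) and 98 from only the arrays compared. The number was 8, 8 and 78 without inoculated replicates 1, 2 and 3 of the Yr39 line, 89, 8 and 9 without its mock replicates, and 11 to 15 without any array of the yr39 line.

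Over both lines and the 3 times TaAffx.32249.1.S1_at was the only call, from 43.7 in mock to 257 in inoculated leaves (log2 2.05, SE 0.264, adjusted p = 0.000413, higher in 17 of 18 pairs), with 2540 probe sets at unadjusted p under 0.05 in limma.

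In inoculated leaves the lines differed in much the same probe sets as in mock leaves. LOC780647 was higher in the Yr39 line by 1.09 (adjusted p = 5.24e-08), LOC780599 by 1.84 (1.36e-05), LOC543152 by 1.59 (0.0121), LOC606363 by 1.26 (5.50e-05), LOC780574 by 1.13 (0.00132) and LOC100125710 by 1.10 (7.04e-05). LOC542853 (−2.07, 4.93e-05), LOC542898 (−2.00, 2.78e-05), LOC543399 (−1.79, 1.83e-06) and LOC542814 (−0.85, 0.000260) were lower. These 10 kept their calls without any single array, but LOC543152 had 1.35 and was not called without all arrays numbered 1 (0.0774), while LOC543018 (0.81, 0.0387) lost it without any one of 14 of the 18 (0.0509 to 0.112). The gibberellin 20-oxidases GA20ox1D (1.18, adjusted p = 0.0648), GA20ox1B (0.28, 0.846) and GA20ox1A (0.35, 0.751) were not called there, and the interaction over the times called no probe set in limma, with 1216 at unadjusted p under 0.05. In all 939 were called (593 higher, 346 lower), and 563 were called in both treatments where 8.8 were expected by chance.

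The first pattern weighed is that the lines differ in the same probe sets in mock and inoculated leaves. Of the 796 probe sets called in mock leaves 98.4% had the same direction in inoculated leaves, on other arrays (r = 0.977), which argues against an effect of the arrays of 1 treatment. Sequence variants under single probe sets remain open. Of 83 calls of at least 4-fold with another probe set of the cluster, 81.9% shared the direction of the mean of those other probe sets (exact binomial p = 3.20e-09). Calls of 1 cluster were counted separately and may share probe sets, so this p rests on an independence that was not checked. The change of that mean was only 0.142 times as large in the median. Variants may therefore lie behind part of the differences, and a true difference in transcript level between these sister lines cannot be told apart from them for those probe sets.

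The second pattern is the size of the change from 24 to 48 h in mock leaves. It called 10.7 times as many probe sets as the step from 12 to 24 h, which argues against the hour of harvest as the cause, since 24 and 48 h fall on the same hour. Of the calls 91.3% kept direction and call after quantile normalization, 89.4% with the hybridization controls as a covariate, 91.7% with the ubiquitin ratio of 3′ to 5′ signal and 84.2% with the GAPDH ratio (−2.30 at 24 and −1.17 at 48 hpi). These values argue against scaling, brightness and what the 2 ratios measure as the whole cause. The mean log2 ratios were below 0, and the ubiquitin ratio moved the other way (−1.37 at 24 and −1.50 at 48 hpi). How well they track RNA integrity is not known, so integrity stays open. On inoculated arrays 97.9% of the mock calls had the same direction (r = 0.948), and of the 1208 calls from 12 to 24 h that were also called from 24 to 48 h in inoculated leaves 1156 had turned, as PEAMT1, FBP and PsbO did in mock leaves. A change in the leaves between 24 and 48 h is a candidate explanation, and the labels name no processing batch, so none was tested.

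The third pattern is that inoculated leaves at 48 hpi lay nearer the 24 h profile than their mock leaves, by more in the Yr39 than in the yr39 line, on a score that is 0 at the mock mean of 24 h and runs along the mock change from 24 to 48 h of the other line. The inoculated and mock scores of the Yr39 line were 0.52 ± 0.10 and 0.67 ± 0.02 (SD, n = 3), a difference of −0.153 (exact permutation p = 0.1, the smallest 3 against 3 can give). In the yr39 line they were 0.82 ± 0.05 and 0.88 ± 0.03 (−0.058, exact permutation p = 0.2). Of the differences between arrays of the same replicate number 6 of 6 were below 0 (exact sign-flip permutation p = 0.0312, the smallest 6 pairs can give). At 12 and 24 hpi such differences ran from −0.133 to 0.103 over both lines. The yr39 differences at 48 hpi (−0.083, −0.04 and −0.051) lay within that range, as did that of Yr39 replicate 3 (−0.074). Those of Yr39 replicates 1 and 2 (−0.237 and −0.149) lay below it. The difference in the Yr39 line stayed at −0.099 or further from 0 without any 1 of the 6 arrays and was −0.154 after quantile normalization, which argues against a single array and against scaling. A slower course of leaf change in inoculated plants is a candidate explanation that was not tested beyond this score. The replicate differences of the 2 lines gave an exact permutation p of 0.2, so a response particular to the resistant line stays open. Of the 6 probe sets called in the Yr39 line at 48 hpi 5 fell from 24 to 48 h in mock leaves of the yr39 line, all but Ta.9415.2.A1_a_at. Over both lines 7022 of the 15456 calls of this mock step were lower. Across probe sets the inoculation change of the Yr39 line at 48 hpi correlated with the mock step of the yr39 line with r = −0.326. For the yr39 line and the mock step of the Yr39 line r was −0.117.

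Other splits of the same arrays were counted for each comparison, the real split included. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In the Yr39 line at 48 hpi the real split called 6 and the highest other 2, with 1 of 10 splits as large, and at 12 and 24 hpi the real and the highest other count were 0, so 10 of 10 were as large each time. In the yr39 line the real count was 0, 1 and 1 at 12, 24 and 48 hpi, the highest other 3, 146 and 19, and 10, 6 and 7 of 10 splits were as large. The split with 146 calls set inoculated replicates 1 and 2 and mock replicate 2 at 24 hpi against the rest, which points to a structure of these arrays other than treatment.

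For the larger comparisons 100 splits were counted. For the interactions at 12, 24 and 48 hpi (real 0; highest other 2, 41 and 42), the Yr39 line over the times (0 and 99), the interaction over the times (0 and 3) and the change with time in the Yr39 line (0 and 1) all 100 splits were as large, since the real count was 0. For the yr39 line 9 of 100 were as large over the times (real 1, highest other 471) and 27 for the change with time (1 and 355), and 6 for the mean over lines and times (1 and 16), so chance was not excluded by these splits, which do not keep replicate numbers together. When inoculated and mock were swapped only within arrays of the same line, time and replicate number, 5 of 100 splits were as large for the mean over lines and times (highest other 1), 5 of 100 for the yr39 line over the times (highest other 3) and 1 of 32 for 48 hpi over both lines (26 and 3), while for the Yr39 line over the times (0 and 2) all 100 were. TaAffx.32249.1.S1_at itself was higher in 17 of 18 pairs. Splits with several times the real count, such as 471 for TaAffx.32249.1.S1_at's comparison, point to a structure of the samples besides treatment. With swaps kept within replicate number the highest other count was 3 in place of 471, 2 in place of 99, 3 in place of 42 and 1 in place of 16. This structure therefore goes at least in part with replicate number, which the main model leaves out. For inoculation at 48 hpi over both lines 4 of 100 were as large (26 and 42). Only the real split, 1 of 100, was as large for the mock steps (1450 and 378, 15456 and 9908), the inoculated steps (1561 and 237, 13393 and 8999) and the lines in mock (796 and 355) and inoculated leaves (939 and 449). A chance division of the arrays is excluded at a share of 0.05 for the planned comparisons among these, the mock steps and the lines in mock leaves. The contrasts in inoculated leaves and the contrast at 48 hpi over both lines were chosen after the data were seen. Chance is therefore not excluded for them, though their shares were under 0.05. At 48 hpi over both lines the highest other split also called 42 against the real 26. The inoculated step from 12 to 24 h called 2383 with replicate number as a block, and 958, 904 and 996 without replicate 1 of inoculated Yr39 leaves at 12 h, of inoculated Yr39 leaves at 24 h and of inoculated yr39 leaves at 12 h.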
